A study of Mus musculus with 18 samples.

How the data were processed

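RNA was sequenced from splenic pan B cells of C57BL/6 mice. Per the labels, the cells first spent 1 h with 1000 ng/ml of a control antibody or of mBaffR-mFc, a BAFF receptor fusion protein described there as blocking the site by which BAFF binds its receptor BR3. They then spent 4 h with 100 ng/ml of BAFF 3mer or BAFF 60mer, the forms of the cytokine with 3 and 60 subunits, or received no BAFF. The 6 groups of 3 libraries are called Ab, Ab_3mer and Ab_60mer (control antibody) and BRFc, BRFc_3mer and BRFc_60mer (mBaffR-mFc). Replicate numbers follow the order of deposition, since the labels give none, and the labels state no pairing of libraries.

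The deposited values were FPKM, fragments per kilobase of gene per M fragments (M, mega), which per the labels a sequencing company computed for the authors. The sources used here name no aligner, counting tool, genome build or scaling between libraries. The table held 35275 Ensembl gene IDs, of which 34490 matched GENCODE mouse release M21 (GRCm38), the source of the symbols and positions. No column of values per sample was left out.

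Library totals were recovered from the steps between the low FPKM values of single-transcript genes. A gene had a step where its values were whole multiples of it to within 0.02. Of 3145 such genes with a step, 2678 (85.2%) gave the same totals. Of the values of single-transcript genes below 500 fragments, 89.1% came out whole to within 0.1. The totals ran from 12.2 to 25.4 M fragments, with a median of 18.4 M. A single fragment on a gene of 1000 bases was worth 0.0393 to 0.0818 FPKM.

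Values were taken as log2(FPKM + 1), so that log2 differences of genes near the floor are smaller than their ratios of FPKM. The 11646 genes with a mean of at least 1 FPKM over all 18 libraries were tested with limma 3.58.1 in R 4.3.3 (moderated test with a trend in the variance, 1 residual variance per gene over the 6 groups). A gene passed at a Benjamini-Hochberg adjusted p under 0.05. Differences are given with their standard error from that model, and group means with the SD of 3 libraries. The p-values measure only the spread between these libraries; the labels do not say whether replicates came from separate animals. The 9 comparisons of 2 groups, 2 interactions and a moderated F test over all groups were set before the data were examined, as were the gene lists and the rule for naming genes.

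The rule allowed a panel of 16 genes, and in each comparison up to 8 genes with the largest rise and 8 with the largest fall. These had to pass the test, reach a mean of 2 FPKM in the higher group, carry a gene symbol that is not a provisional name and show no overlap between the libraries of the groups compared, which chance gives in 10% of genes. Where fewer than 3 passed, the 3 smallest p-values were named. It also allowed up to 4 passing members of each list, or 2 values where none passed. Some were left out for length.

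Of 37 gene lists, 36 had at least 3 tested members; the list of erythroid markers had 2 and was not tested. Lists were compared with all other genes by camera of limma with a preset correlation of 0.01 and adjusted over the 36 lists of a comparison, with an estimated correlation and with fry beside it. Fry asks whether the members move on balance in a single direction, without comparing them with other genes. Some lists share members. Birc2 and Birc3 are in the lists of NF-kB subunits and of pro-survival genes. Bcl2l1, Pim1, Pim2, Bcl2a1a, Bcl2a1b and Bcl2a1d are in those of NF-kB targets and of pro-survival genes.

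Alternatives were another pseudocount (0.1), no filter or a minimum mean of 5 FPKM, median-of-ratios rescaling, quality weights, a fit of only the groups compared, and leaving out each library in turn. Chosen after seeing the data were the library total, the first residual component (23.1% of residual variation) or the presence of connective tissue transcripts as a term, voom on recovered fragments, a correction for GC content and length, which 99.3% of the tested genes had, leaving out the Ab_3mer libraries with connective tissue transcripts, and the position of a library in the order of deposition as a block. The block was also added to the comparison among carrying libraries, since the carrying Ab_3mer libraries are those at positions 1 and 2.

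The steps were tested on simulated data with the spread of the real genes, with 200 of 11646 genes changed in each of 10 sets. The test of 3 against 3 libraries recovered 55.2% of changes of 1.25-fold, 85.8% of 1.5-fold and 95.9% of 2-fold, with 4.6% false calls. The interaction test recovered 25.1%, 65.5% and 89.2%. In a simulated trend with GC content and length, the correction brought the median standard error from 0.217 back to 0.075 and the mean of genes changed by a log2 of 0.585 came out at 0.58. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.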

Results

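The data describe the transcriptome of splenic mouse B cells after 4 h with BAFF 3mer, BAFF 60mer or no BAFF, each after control antibody or mBaffR-mFc, in 6 groups of 3 libraries. The design asks what each form of BAFF does to B cell transcripts and whether blocking the BR3-binding site of BAFF changes it. Mean library totals ran from 14.9 ± 2.59 M fragments in Ab_60mer to 21.6 ± 3.5 M in BRFc (SD, n = 3). Over all groups, 1040 of 11646 genes passed the F test of limma. Transcripts of connective tissue split the libraries in a way the groups do not explain. The summed FPKM of 6 such genes, Col1a1, Col1a2, Col3a1, Sparc, Dcn and Bgn, lay between 8.14 and 12.9 in 8 libraries, replicates 1 and 2 of Ab_3mer and all of Ab_60mer and BRFc_60mer, and between 0 and 0.13 in the other 10. Comparisons of BAFF 60mer with no BAFF, and with BAFF 3mer under mBaffR-mFc, lie wholly across this split. For them each account also gives Ab_60mer against the 2 Ab_3mer libraries that carry these transcripts, called the comparison among carrying libraries.

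**Figure D1:**
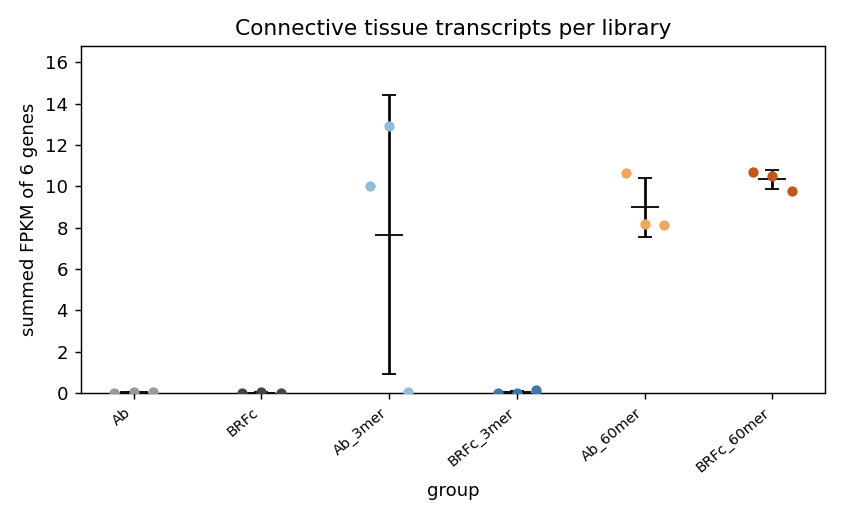
Summed FPKM of 6 connective tissue genes (vertical axis) for each of the 18 libraries, by group (horizontal axis), with dots for libraries and bars for the mean and SD of 3. The 8 carrying libraries lie between 8.14 and 12.9 and the other 10 between 0 and 0.13.

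BAFF 60mer under control antibody raised genes of the NF-kB and survival lists. Kynu, which encodes kynureninase of the tryptophan breakdown pathway, rose from 23.9 ± 0.781 to 46.8 ± 0.064 FPKM (SD, n = 3), by 0.94 ± 0.049 on the log2 scale (SE; adjusted p = 9.8e-09). S1pr1, the sphingosine 1-phosphate receptor that guides lymphocytes out of lymphoid tissue, fell from 117.9 ± 3.73 to 79.0 ± 2.41 FPKM, a log2 difference of -0.57 ± 0.035 (adjusted p = 5.79e-08). Sdc1, the plasma cell surface proteoglycan syndecan 1, had a log2 difference of -0.87 ± 0.078. Among the other large rises were Asb2 (log2 difference 0.96 ± 0.15), the lysosomal trafficking regulator Lyst (0.90 ± 0.095) and Nav2 (0.87 ± 0.12). Among the large falls were the long noncoding RNA Neat1 (-0.85 ± 0.099), B3gnt8 (-0.84 ± 0.147), Nrgn (-0.84 ± 0.18), Ccne1, a G1 cyclin (-0.82 ± 0.112), and Cdkn2d (-0.79 ± 0.157). Col3a1, a collagen gene among the connective tissue transcripts, also passed as higher, with 3.24 ± 0.452 FPKM against a listing at 0 in Ab, and was at -0.38 ± 0.135 among carrying libraries (adjusted p = 0.189).

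Of the list of NF-kB subunits and feedback genes, 6 of 21 members rose, 1 fell and 14 did not pass (9 rose and 1 fell adjusted over the list alone). Birc3, an inhibitor of apoptosis, rose by 0.35 ± 0.036, the inhibitor gene Nfkbie by 0.36 ± 0.041, Traf1 by 0.36 ± 0.054 and Traf3 by 0.27 ± 0.051. Nfkb2, the precursor subunit of the noncanonical pathway, rose by 0.28 ± 0.081 (adjusted p = 0.0336), and Relb, its partner, was at 0.01 ± 0.044 (adjusted p = 0.855). Of 30 NF-kB targets in B cells, 9 rose and 21 did not pass (13 rose and 1 fell adjusted over the list alone), among them Cd44 (0.55 ± 0.044), Cd40 (0.41 ± 0.061) and Il2ra (0.40 ± 0.058). Of 16 pro-survival genes, 5 rose and 11 did not pass (9 rose adjusted over the list alone). These included Bcl2l1, which encodes BCL-XL (0.53 ± 0.075), the kinase gene Pim2 (0.44 ± 0.085) and the caspase 8 inhibitor Cflar (0.24 ± 0.042), while Mcl1 was at -0.02 ± 0.049. Of 16 pro-apoptotic genes, Casp8 (-0.24 ± 0.053) and Bmf (-0.30 ± 0.067) fell, Bid rose by 0.19 ± 0.058 and 13 did not pass. The first 3 lists passed camera (adjusted p = 6.2e-05, 8.9e-06 and 0.0013), and each did with an estimated correlation (adjusted p = 0.024, 0.027 and 0.024). The pro-apoptotic list did not pass camera (adjusted p = 0.34). The pro-survival list shares members with the NF-kB lists, Birc3, Bcl2l1 and Pim2 among them, so these 3 lists are not separate findings.

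Genes of B cell subsets moved both ways. Of 18 marginal zone genes, 5 rose and 5 fell, with Plxnd1 up by 0.35 ± 0.064 and Rasgrp2 at -0.49 ± 0.082. Of 13 follicular genes, Fcer2a, the CD23 gene (0.35 ± 0.04), and the chemokine receptor Cxcr5 (0.16 ± 0.034) rose, and the transcription factor Klf2 (-0.52 ± 0.062) and Itgb7 (-0.65 ± 0.136) fell. Of 24 genes of B cell receptor signalling, 3 rose and 4 fell. The inhibitory receptors Fcgr2b (-0.45 ± 0.063) and Cd22 (-0.24 ± 0.043) and the kinase Btk (-0.19 ± 0.039) fell, and Prkcb rose by 0.23 ± 0.042. Spib rose by 0.36 ± 0.04, with 2 of the 10 transitional and immature genes up and 1 down. Tnfrsf13b, the gene of the BAFF receptor TACI, fell (-0.20 ± 0.042), Tnfrsf13c, the gene of BR3, was at -0.07 ± 0.039 (adjusted p = 0.248), and Cr2, which encodes complement receptor 2, rose by 0.21 ± 0.045. None of these 5 lists passed camera (adjusted p = 0.99, 0.4, 0.68 and 0.39, and 0.73 for the BAFF and APRIL receptors and ligands). The tests of the marginal zone and follicular lists point up, with medians of -0.02 and 0.04 and means of -0.01 and -0.03.

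Of 20 genes of B cell activation and costimulation, 4 rose and 1 fell, among them Cd44, Cd40 and Il2ra (adjusted p = 0.017; 0.59 with an estimated correlation). Of 29 cell cycle genes, Ccnd2, cyclin D2 (0.62 ± 0.066), and Top2a (0.27 ± 0.064) rose and Ccne1 fell. Of 14 plasma cell genes, Pou2af1 rose by 0.35 ± 0.051 and Sdc1 fell. In MHC class II presentation, Ifi30 (0.48 ± 0.059) was among 2 that rose, and H2-Ob fell (-0.25 ± 0.044). Klf4 (-0.53 ± 0.084), Btg2 (-0.23 ± 0.036) and Ier2 (-0.30 ± 0.074) were among 4 of 24 immediate early genes that fell. The cytokine genes Ebi3 (0.56 ± 0.115), Il12a (0.40 ± 0.077) and Lta (0.37 ± 0.105) rose, and the transporters Slc1a5 (-0.26 ± 0.048) and Slc16a3 (-0.43 ± 0.096) fell. These last 6 lists did not pass camera (adjusted p = 0.32, 0.91, 0.4, 0.11, 0.94 and 0.94 in that order). The test of the plasma cell list points up with a median of -0.002 and a mean of -0.05, and that of the glycolysis and amino acid list down with a median of 0.001. Of 22 cholesterol synthesis genes, Hmgcs1 (0.24 ± 0.062) and Lss (0.24 ± 0.076) rose (adjusted p = 0.028; 0.59 with an estimated correlation). The lists of MYC and ribosome biogenesis (1 of 22 rose, adjusted p = 0.012), immunoglobulin V segments (4 of 181 rose, 0.023) and type I interferon response (0 of 27 passed, median -0.22, 0.047) also passed camera, and with an estimated correlation had adjusted p = 0.59, 0.59 and 0.82. Markers of other cells moved as well. Il2rb (-0.30 ± 0.054), Klre1 (-0.47 ± 0.108) and Klrd1 (-0.28 ± 0.07) were the 3 of 12 NK cell genes that fell (adjusted p = 0.028; 0.38 with an estimated correlation), and the dendritic cell gene Zbtb46 rose by 0.62 ± 0.093.

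In all, 587 genes were higher and 1041 lower after BAFF 60mer (limma), so that 36.1% of the calls were rises, against 47.9% with median-of-ratios rescaling (786 and 856). The median size of the called changes was 0.29 on the log2 scale, and 78 rises and 38 falls exceeded 1.5-fold. All libraries of Ab_60mer carry the connective tissue transcripts and none of Ab does. Among carrying libraries, 103 genes were higher and 143 lower; of the 1628 called genes, chosen with the same Ab_60mer libraries, 233 passed there, and their median in the called direction was 0.18. Of the genes named above, Kynu (0.85 ± 0.052), Sdc1 (-0.84 ± 0.085), S1pr1 (-0.55 ± 0.04), Nfkbie, Birc3, Nfkb2, Traf1, Traf3, Cd44, Cd40, Il2ra, Bcl2l1, Pim2, Fcer2a, Spib, Klf2, Ccnd2 and Pou2af1 passed there. In this smaller test, of 3 libraries against 2, other genes did not pass but had differences near those above, among them Bid (0.19), Lta (0.41), Lss (0.25), Ier2 (-0.28), Top2a (0.23), Cxcr5 (0.14) and Slc16a3 (-0.39). Somewhat smaller were those of Casp8 (-0.17), Bmf (-0.23), Cd22 (-0.16), Itgb7 (-0.52), Tnfrsf13b (-0.15), H2-Ob (-0.18), Klre1 (-0.35), Nrgn (-0.57) and Cdkn2d (-0.52), which did not pass either. The differences of Cflar (0.12), Cr2 (0.12), Hmgcs1 (0.11), Slc1a5 (-0.12), Il2rb (-0.10), Ebi3 (0.11) and Klrd1 (-0.07) did not pass and were the smallest beside those above. Neat1 passed there with a smaller difference of -0.42 ± 0.1. Of the lists past camera, NF-kB subunits (median 0.09), NF-kB targets (0.14) and pro-survival genes (0.13) passed there also with an estimated correlation (adjusted p = 0.012, 0.036 and 0.012), with the same Ab_60mer libraries. Cholesterol synthesis (0.09) and V segments (0.06) passed camera there (adjusted p = 0.017 and 0.0093; 0.88 and 0.54 with an estimated correlation). B cell activation had a median of -0.11 there with a test that pointed up (adjusted p = 0.84), MYC and ribosome biogenesis 0.02 (0.52), interferon genes -0.04 (0.8) and NK cell genes -0.04 (0.71), and none of these 4 passed. The carrying Ab_3mer libraries lack position 3 in the order of deposition. With that position as a block 482 genes passed among carrying libraries, 427 of them among the 1628, and of the genes above Bmf (-0.26), Itgb7 (-0.62), Cd22 (-0.18), H2-Ob (-0.19) and Ier2 (-0.30) now did. The same 5 lists passed camera with the block, cholesterol synthesis and V segments not with an estimated correlation (adjusted p = 0.89 and 0.44). B cell activation was at -0.10, and interferon genes at -0.12 (adjusted p = 0.88 and 0.14 in camera). The count fell to 823 and 1000 without Ab replicates 1 and 2, and to 756 and 983 without Ab_60mer replicates 1 and 2. The number of lists past camera fell from 9 to 4 without Ab replicate 3. Nfkb2 did not pass without Ab replicate 1 (adjusted p = 0.0927) or 2 (0.11) or Ab_60mer replicate 2 (0.0554) or 3 (0.118). The fits that leave out a library do not include the position as a block, and Nfkb2 was highest at position 3 in each group. With the block it was at 0.39 ± 0.05 among carrying libraries (limma, adjusted p = 0.000688). Without Ab replicate 2, Bid (0.126), Lta (0.0869), Klrd1 (0.0581), Hmgcs1 (0.0561) and Lss (0.192) did not pass, and without Ab replicate 1 Hmgcs1 (0.0708), Lss (0.0923) and Top2a (0.0666) did not. Bid (0.107) and Lta (0.0691) did not pass without Ab replicate 3. Without Ab_60mer replicate 1, Bid (0.176), Ier2 (0.0783), Lta (0.127), Klrd1 (0.0734) and Lss (0.0553) did not pass. Without Ab_60mer replicate 2, Bid (0.115), Hmgcs1 (0.0896), Lss (0.118) and Top2a (0.0512) did not, nor did Lss without Ab_60mer replicate 3 (0.11). Of the lists, only NF-kB subunits, NF-kB targets and pro-survival genes passed camera without each library in turn. Without Ab replicate 3 the adjusted p was 0.067 for B cell activation, 0.058 for MYC and ribosome biogenesis, 0.079 for cholesterol synthesis, 0.42 for interferon genes and 0.079 for V segments, and without Ab replicate 1 it was 0.051 for NK cell genes. Without Ab_60mer replicate 1 it was 0.066 for B cell activation and 0.066 for interferon genes, without replicate 2 0.12 for cholesterol synthesis and 0.35 for interferon genes, and without replicate 3 0.09 for cholesterol synthesis and 0.077 for V segments.

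**Figure D2:**
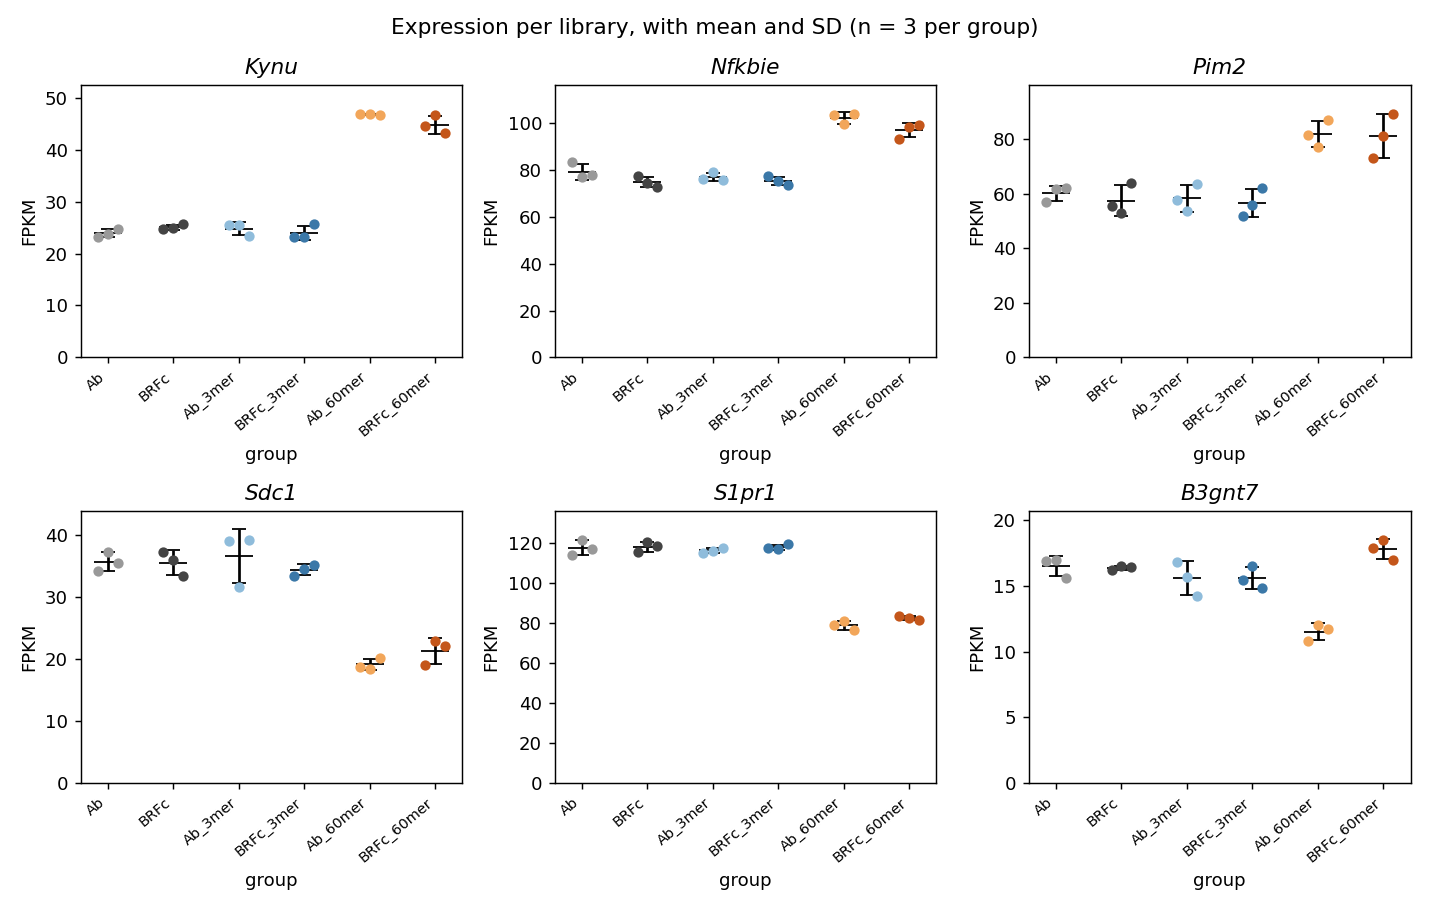
FPKM (vertical axes) of Kynu, Nfkbie, Pim2, Sdc1, S1pr1 and B3gnt7 in each of 18 libraries, by group (horizontal axes), with dots for libraries and bars for the mean and SD of 3. Kynu had a mean of 46.8 in Ab_60mer and 44.8 in BRFc_60mer, against 23.9 in Ab and 25.1 in BRFc.

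BAFF 3mer under control antibody left no gene past the threshold (limma, 0 also with voom; 632 genes at an unadjusted p under 0.05, where chance gives 582). Kynu stood at 24.8 ± 1.23 FPKM and S1pr1 at 116.5 ± 1.29 FPKM in Ab_3mer (SD, n = 3), beside 23.9 and 117.9 in Ab. The panel of 16 genes ran from -0.09 on the log2 scale for Nfkb2 to 0.21 for Myc, with confidence limits of 95% between -0.26 and 0.52. The smallest p-values belonged to Coq2 (-0.20 ± 0.042; adjusted p = 0.436), Stambpl1 (-0.25 ± 0.051) and Jmjd6 (-0.21 ± 0.045), none of which passed. Camera gave higher values of B cell activation genes (median 0.08), transitional genes (0.05) and replication histones (0.15) and lower ones of NK cell genes (-0.17), and with an estimated correlation the adjusted p was 0.69, 0.53, 0.77 and 0.53. The count was 1 without Ab replicate 1 and 1 without Ab_3mer replicate 3, the only library of its group that does not carry connective tissue transcripts, and 1 without the other 2. On simulated data the test recovered 85.8% of changes of 1.5-fold, but 55.2% of the smallest changes simulated. Of the 1628 changes called for BAFF 60mer under control antibody, only 78 rises and 38 falls exceeded 1.5-fold, and their median size was 0.29. A response to BAFF 3mer of that median size in a single gene could therefore have been missed. The 563 genes called for BAFF 60mer under mBaffR-mFc, a set chosen afterwards from other libraries, were also read here. Their mean in the called direction was 0.042 ± 0.029 for BAFF 3mer under control antibody, with an upper bound of 0.1 at 2 standard errors. For BAFF 60mer under control antibody it was 0.297 ± 0.029. This argues against a response of these genes as a set to BAFF 3mer as large as that to BAFF 60mer.

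**Figure D3:**
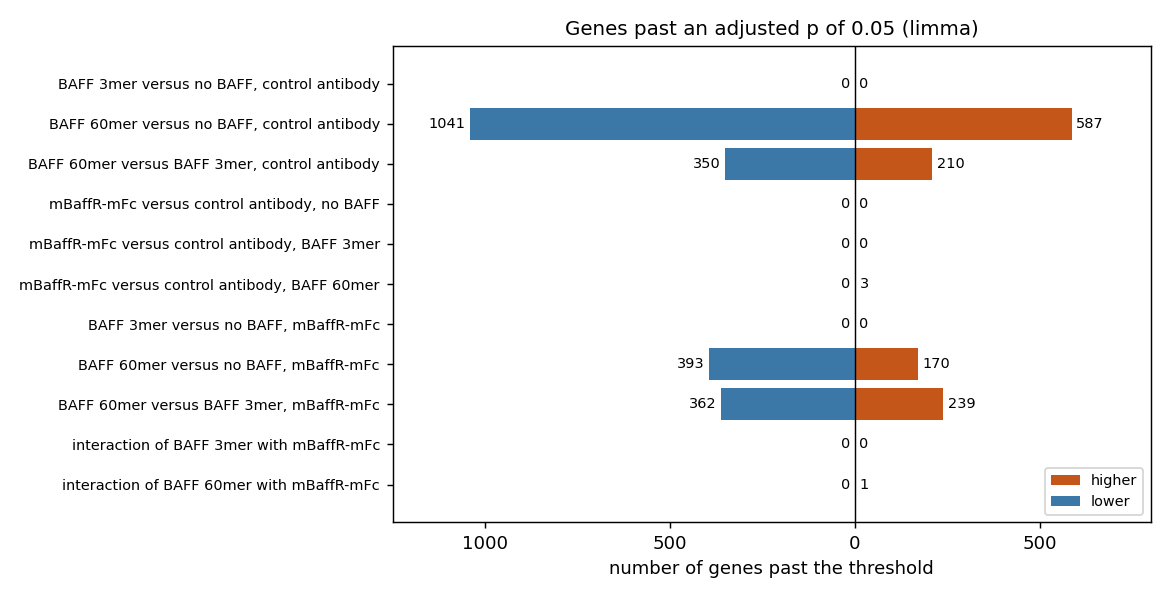
Number of genes (horizontal axis) higher to the right and lower to the left in each of the 9 comparisons and 2 interactions (vertical axis), at an adjusted p of 0.05 in limma. The counts run from 0 to 587 for higher and from 0 to 1041 for lower.

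The direct comparison of BAFF 60mer with BAFF 3mer under control antibody asks whether the forms differ at the same dose and time. Kynu (0.89 ± 0.049), Asb2 (1.03 ± 0.15), the basement membrane gene Nid1 (0.65 ± 0.079) and the transcription factor Lef1 (0.62 ± 0.088) were higher with BAFF 60mer. Sdc1 (-0.90 ± 0.078), the sphingosine 1-phosphate transporter Spns2 (-0.71 ± 0.109), Serpinb1a (-0.61 ± 0.065), Plk2 (-0.59 ± 0.065) and S1pr1 (-0.55 ± 0.035) were lower. Of NF-kB subunits and feedback genes 6 of 21 were higher, with Nfkbie at 0.40 ± 0.041, Birc3 at 0.34 ± 0.036 and Nfkb2 at 0.36 ± 0.081. Of NF-kB targets 8 of 30 were higher, with Cd40 at 0.49 ± 0.061 and Cd44 at 0.41 ± 0.044, and of pro-survival genes 3 of 16, with Pim2 at 0.48 ± 0.085 and Bcl2l1 at 0.47 ± 0.075. These 3 lists, which share members such as Birc3, Pim2 and Bcl2l1, passed camera also with an estimated correlation (adjusted p = 0.012, 0.022 and 0.013). Camera called immediate early genes lower, 3 of 24 passing, with Klf4 at -0.45 ± 0.084, Btg2 at -0.24 ± 0.036 and Ier2 at -0.28 ± 0.074 (adjusted p = 0.00027; 0.84 with an estimated correlation), and cholesterol synthesis genes higher, 1 of 22 passing (0.0059; 0.84 with an estimated correlation). Fcer2a (0.35 ± 0.04) and Ccnd2 (0.57 ± 0.066) were higher and Klf2 (-0.44 ± 0.062) lower; Lta (0.45 ± 0.105) passed, and Cr2 (0.14 ± 0.045; adjusted p = 0.0891) did not.

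In all, 210 genes were higher and 350 lower with BAFF 60mer than with BAFF 3mer (limma; 37.5% higher, and 39.2% with median-of-ratios rescaling), of which 181 and 317 were also called against no BAFF. The comparison among carrying libraries, which uses 5 of the same 6 libraries and so is no separate evidence, had 246 calls, 241 of them among the 560. The count fell to 318 and 246 without Ab_3mer replicates 1 and 3 and to 259 and 353 without Ab_60mer replicates 1 and 2. Ab_3mer replicate 3 is the only library of its group that does not carry connective tissue transcripts. Leaving it out, or adding the connective tissue term, therefore gives the comparison among carrying libraries again, with the same 246 calls, and is no further check. Nfkb2 did not pass without Ab_3mer replicates 1 (adjusted p = 0.0513) or 2 (0.0702) or Ab_60mer replicate 3 (0.0645). Ier2 did not without Ab_3mer replicates 1 (0.167) or 3 (0.121) or Ab_60mer replicates 1 (0.177), 2 (0.0612) or 3 (0.0506). Lta did not without Ab_3mer replicates 1 (0.0615) or 3 (0.0961) or Ab_60mer replicate 1 (0.102). The test of B cell activation genes pointed up (adjusted p = 0.51) with a median of -0.06 and a mean of 0.01.

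Under mBaffR-mFc, BAFF 60mer again raised Kynu and lowered S1pr1. Kynu rose by 0.81 ± 0.049 (adjusted p = 9.91e-08), from 25.1 ± 0.495 to 44.8 ± 1.74 FPKM, and S1pr1 had a log2 difference of -0.51 ± 0.035, from 118.3 ± 2.42 to 82.7 ± 0.961 FPKM (SD, n = 3). Il4i1, an amino acid oxidase gene (1.03 ± 0.098), Gadd45g (0.85 ± 0.16), Asb2 (0.84 ± 0.15) and Ticam2 (0.69 ± 0.082) rose, and Ccne1 (-0.77 ± 0.112), Acp5 (-0.77 ± 0.105) and Sdc1 (-0.72 ± 0.078) fell. Spp1, the osteopontin gene, rose by 1.15 ± 0.139, the immunoglobulin constant gene Ighg1 by 1.38 ± 0.274, and Col3a1 passed as higher, with 3.96 ± 0.213 FPKM against a listing at 0 in BRFc. Among carrying libraries Spp1 was lower with BAFF 60mer and passed (-0.54 ± 0.13), and Col3a1 (-0.38 ± 0.135) and Ighg1 (-0.30 ± 0.187) did not pass.

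Of NF-kB subunits and feedback genes 5 of 21 rose (8 adjusted over the list alone), with Birc3 at 0.33 ± 0.036, Nfkbie at 0.37 ± 0.041, Nfkbia at 0.39 ± 0.059, Traf1 at 0.28 ± 0.054 and Nfkb2 at 0.39 ± 0.081. Of NF-kB targets 9 of 30 rose (13 adjusted over the list alone), with Cd44 at 0.36 ± 0.044, Icam1 at 0.34 ± 0.054 and Cd40 at 0.35 ± 0.061. Of pro-survival genes 4 of 16 rose (6 adjusted over the list alone), with Pim2 at 0.49 ± 0.085, Bcl2l1 at 0.33 ± 0.075 and Pim1 at 0.21 ± 0.056. These lists passed camera also with an estimated correlation (adjusted p = 0.0011, 0.0051 and 0.0045). Birc3, Pim2, Bcl2l1 and Pim1 are in the pro-survival list and in an NF-kB list, so the lists are not separate findings. Of 22 cholesterol synthesis genes 6 rose (11 adjusted over the list alone), among them Hmgcs1 (0.32 ± 0.062), Idi1 (0.33 ± 0.067) and Cyp51 (0.29 ± 0.061); with an estimated correlation the adjusted p was 0.097. Of 27 type I interferon genes, Mx1 (-0.72 ± 0.158) and Irf7 (-0.68 ± 0.185) fell (8 adjusted over the list alone); the list's median was -0.38, and with an estimated correlation the adjusted p was 0.38. Neither gene differed detectably among carrying libraries (Mx1 -0.07 ± 0.179, Irf7 -0.07 ± 0.208), and Mx1 did not pass without BRFc replicate 3 (adjusted p = 0.0847) or BRFc_60mer replicate 2 (0.0632), nor Irf7 without BRFc replicates 2 (0.109) or 3 (0.24) or BRFc_60mer replicates 1 (0.113) or 2 (0.204). Fcer2a (0.51 ± 0.04), Gpr183 (0.56 ± 0.086), the germinal centre regulator Bcl6 (0.40 ± 0.05), the class II transactivator Ciita (0.25 ± 0.057), Ifi30 (0.45 ± 0.059), Cr2 (0.29 ± 0.045) and Cd83 (0.48 ± 0.118) rose. Klf2 (-0.40 ± 0.062), Tnfrsf13b (-0.21 ± 0.042), Tnfrsf13c (-0.15 ± 0.039), Tnfrsf14 (-0.47 ± 0.101), the pro-apoptotic Bcl2l11 (-0.21 ± 0.051) and the stress genes Trib3 (-0.44 ± 0.081) and Ddit3 (-0.29 ± 0.072) fell. The lists of B cell activation, MHC class II, class switching, MYC and ribosome biogenesis, mitochondrially encoded genes and ribosomal proteins were higher in camera, and with an estimated correlation had adjusted p = 0.32, 0.098, 0.096, 0.32, 0.24 and 0.7.

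In all, 170 genes were higher and 393 lower (limma), 30.2% of them rises, against 44.4% with median-of-ratios rescaling. All libraries of BRFc_60mer carry connective tissue transcripts and none of BRFc does. Among carrying libraries under control antibody, which share no library with those compared here, 537 of the 563 genes had the same direction and 165 passed. Of the genes named here that did not pass there, Bcl2l11 (-0.19), Icam1 (0.24), Tnfrsf13b (-0.15), Ciita (0.17) and Trib3 (-0.29) had differences nearest to those above. Nfkbia (0.21), Bcl6 (0.15), Cr2 (0.12), Tnfrsf13c (-0.07), Pim1 (0.08), Hmgcs1 (0.11), Idi1 (0.13), Cyp51 (0.12), Acp5 (-0.34) and Gadd45g (0.24) had smaller ones, and Gpr183 (0.006), Cd83 (-0.04) and Tnfrsf14 (0.003) were near 0. With the position as a block these last 3 were at 0.06 ± 0.059, 0.05 ± 0.056 and -0.02 ± 0.111, still far below the differences under mBaffR-mFc, 265 of the 563 genes passed, and Nfkbia (0.24), Icam1 (0.24) and Acp5 (-0.39) were among them. Il4i1 passed there with a smaller difference of 0.53 ± 0.11. Of the lists, the 3 of NF-kB and survival genes and cholesterol synthesis passed camera there (adjusted p = 1.1e-05, 1.1e-05, 9.2e-05 and 0.017), the last not with an estimated correlation (adjusted p = 0.88). B cell activation (median -0.11; adjusted p = 0.84), MHC class II (-0.01; 0.52), class switching (-0.02; 0.84), MYC and ribosome biogenesis (0.02; 0.52), mitochondrially encoded genes (0.11; 0.43), ribosomal proteins (0.001; 0.84) and interferon genes (-0.04; 0.8) did not. The count was 306 and 242 without BRFc replicates 2 and 3, and 340 and 321 without BRFc_60mer replicates 1 and 2. The list of ribosomal proteins had a mean of 0.05 with all libraries and -0.06 without BRFc replicate 3, and did not pass camera without BRFc_60mer replicate 3 (adjusted p = 0.31), nor did B cell activation without BRFc_60mer replicate 1 (0.069). Calls that ended without BRFc replicate 3 were those of Idi1 (0.0563), Cyp51 (0.0697), Bcl2l1 (0.0962), Bcl2l11 (0.0744), Tnfrsf13c (0.12), Tnfrsf14 (0.0697), Ddit3 (0.0783) and Cd83 (0.154). Without BRFc replicate 2 they were those of Pim1 (0.156), Bcl2l11 (0.0828), Tnfrsf13c (0.0647), Tnfrsf14 (0.0506), Ddit3 (0.09) and Cd83 (0.0808), and without BRFc replicate 1 those of Pim1 (0.0673), Bcl2l11 (0.0509) and Tnfrsf13c (0.0847). Without BRFc_60mer replicate 2 they were those of Idi1 (0.0533), Cyp51 (0.0535), Ciita (0.0801), Bcl2l1 (0.0563), Bcl2l11 (0.0926), Ddit3 (0.0878) and Cd83 (0.0883). Without BRFc_60mer replicate 1 they were those of Pim1 (0.147), Bcl2l1 (0.0532), Tnfrsf13c (0.143), Tnfrsf14 (0.0568) and Cd83 (0.0986), and without replicate 3 those of Pim1 (0.0829), Bcl2l11 (0.0907), Tnfrsf13c (0.0912) and Ddit3 (0.0827).

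BAFF 60mer and BAFF 3mer also differed under mBaffR-mFc. Kynu (0.87 ± 0.049), Il4i1 (1.04 ± 0.098), the sulfotransferase gene Chst10 (0.64 ± 0.065), Fcer2a (0.49 ± 0.04) and Cr2 (0.32 ± 0.045) were higher with BAFF 60mer. Ccne1 (-0.81 ± 0.112), Hepacam2 (-0.70 ± 0.102), Sdc1 (-0.67 ± 0.078), Spns2 (-0.67 ± 0.109), Ceacam1 (-0.61 ± 0.092) and S1pr1 (-0.51 ± 0.035) were lower. Of NF-kB subunits and feedback genes 6 of 21 were higher, with Nfkb2 at 0.43 ± 0.081, Birc3 at 0.36 ± 0.036 and Nfkbie at 0.36 ± 0.041. Of NF-kB targets 6 of 30 and of pro-survival genes 4 of 16 were higher, and these lists passed also with an estimated correlation (adjusted p = 0.003, 0.029 and 0.003). Of cholesterol synthesis genes 8 of 22 were higher, with Idi1 at 0.36 ± 0.067, Cyp51 at 0.33 ± 0.061, Sqle at 0.34 ± 0.073 and Hmgcs1 at 0.31 ± 0.062 (0.054 with an estimated correlation). Ifi27l2a (-0.46 ± 0.102) and Bst2 (-0.32 ± 0.078) were the 2 of 27 interferon genes that were lower (adjusted p = 1.4e-07; 0.48 with an estimated correlation). Camera called class switching genes (2 of 12 passing), MYC and ribosome biogenesis (2 of 22) and mitochondrially encoded genes (0 of 12) higher, and immediate early genes (2 of 24) and ribosomal proteins (0 of 74) lower (adjusted p = 0.0071, 5.8e-05, 0.039, 0.019 and 0.014). With an estimated correlation none of these passed (adjusted p = 0.05, 0.46, 0.49, 0.57 and 0.83). Ciita (0.35 ± 0.057) and Bcl6 (0.40 ± 0.05) were higher and Tnfrsf13c (-0.19 ± 0.039) lower, and Spp1 (1.17 ± 0.139), Ighg1 (1.51 ± 0.274) and Col3a1 (3.96 ± 0.213 against 0.021 ± 0.036 FPKM) were higher.

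In all, 239 genes were higher and 362 lower (limma), 39.8% of them higher, against 48.6% with median-of-ratios rescaling (301 and 318). Every library of BRFc_60mer and none of BRFc_3mer carries connective tissue transcripts; 181 of the 601 genes passed among carrying libraries and 577 had the same direction. Of the genes named here that did not pass there, Ceacam1 was at -0.39, Sqle at 0.17, Ciita at 0.17, Bcl6 at 0.15, Idi1 at 0.13, Cr2 at 0.12, Cyp51 at 0.12, Hmgcs1 at 0.11, Ifi27l2a at -0.16, Tnfrsf13c at -0.07, Bst2 at 0.002, Ighg1 at -0.30 and Col3a1 at -0.38. Spp1 passed as lower, and Il4i1 passed at 0.53. Of the lists, the 3 of NF-kB and survival genes, cholesterol synthesis (median 0.09) and immediate early genes (-0.30) passed camera there, the last 2 not with an estimated correlation (adjusted p = 0.88 and 0.38). Class switching (-0.02), MYC and ribosome biogenesis (0.02), mitochondrially encoded genes (0.11), ribosomal proteins (0.001) and interferon genes (-0.04) did not (adjusted p = 0.84, 0.52, 0.43, 0.84 and 0.8). With the position as a block 267 of the 601 passed, Ceacam1 (-0.40) among them, and immediate early genes were at -0.25. The count was 270 and 233 without BRFc_3mer replicates 2 and 3 and 343 without BRFc_60mer replicate 2. Without BRFc_3mer replicate 3, Hmgcs1 (adjusted p = 0.051), Sqle (0.0714), Ifi27l2a (0.078) and Bst2 (0.0822) did not pass, and without BRFc_60mer replicate 2 Sqle (0.0698), Ifi27l2a (0.0741) and Bst2 (0.127) did not. Ifi27l2a (0.0559) and Bst2 (0.082) also did not without BRFc_3mer replicate 2, nor Bst2 without replicate 1 of BRFc_3mer (0.059) or BRFc_60mer (0.0908).

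BAFF 3mer under mBaffR-mFc left no gene past the threshold (limma, 0 also with voom; 388 genes at an unadjusted p under 0.05, where chance gives 582). Kynu was at 24.0 ± 1.4 FPKM (SD, n = 3). The panel ran from -0.06 for Tnfrsf13b to 0.27 for Bcl2a1b, a gene with near-identical copies whose reads cannot be assigned with certainty, with confidence limits between -0.21 and 0.61. Zfyve21 (0.44 ± 0.106), Cklf (0.32 ± 0.078) and Minpp1 (-0.20 ± 0.049) had the smallest p-values (adjusted p = 0.999). Camera called 6 lists higher, ribosomal proteins (median 0.14), oxidative phosphorylation (0.06), B cell activation (0.14), immediate early genes (0.07), cytokines (0.07) and immunoglobulin V segments (0.03). With an estimated correlation their adjusted p was 0.72, and 0.75 for immediate early genes. The count was 1 without BRFc_3mer replicate 1.

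mBaffR-mFc changed no gene past the threshold without BAFF (limma, 0 also with voom in both; 688 genes at an unadjusted p under 0.05, where chance gives 582) or with BAFF 3mer (452 genes). Without BAFF the smallest p-values were those of Pex16 (-0.30 ± 0.062), Jmjd6 (-0.21 ± 0.045) and Stambpl1 (-0.23 ± 0.051), each at adjusted p = 0.829. With BAFF 3mer they were those of Spp1 (-0.62 ± 0.139), Apobec2 (-0.46 ± 0.104) and Apool (0.43 ± 0.1), each at adjusted p = 0.998. Spp1 was at 4.04 and 3.32 FPKM in the Ab_3mer libraries that carry connective tissue transcripts and at 2.3 in the other. The panel lay between -0.25 and 0.09 without BAFF and between -0.14 and 0.08 with BAFF 3mer. Camera called ribosomal proteins lower without BAFF (median -0.08; 0.85 with an estimated correlation) and higher with BAFF 3mer (0.06; 0.78). It also called MYC and ribosome biogenesis lower in both (0.81 and 0.32), oxidative phosphorylation lower without BAFF (0.81), and, with BAFF 3mer, glycolysis (0.31) and immunoglobulin constant genes (0.18) lower and interferon (0.61) and NK cell genes (0.24) higher. The counts were 1 without Ab replicate 1 in the comparison without BAFF and 1 without Ab_3mer replicate 3 in that with BAFF 3mer.

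With BAFF 60mer, 3 genes were higher and 0 lower under mBaffR-mFc than under control antibody (limma, 2 and 0 with voom, and 540 genes at an unadjusted p under 0.05). B3gnt7, which encodes a glycosyltransferase of glycan chains, stood at 11.5 ± 0.639 FPKM in Ab_60mer and 17.8 ± 0.767 in BRFc_60mer (SD, n = 3), a log2 difference of 0.59 ± 0.063 (adjusted p = 0.000573). Its mean was 16.5 ± 0.747 in Ab and 16.4 ± 0.155 in BRFc, so it fell with BAFF 60mer under control antibody but not under mBaffR-mFc. Pkib, a protein kinase inhibitor gene, went from 15.9 ± 1.92 to 24.6 ± 1.63 FPKM (0.60 ± 0.081; adjusted p = 0.00705), and Spp1 from 2.21 ± 0.19 to 5.14 ± 0.604 (0.93 ± 0.139; adjusted p = 0.0163). All 6 libraries carry connective tissue transcripts. The panel lay between -0.19 for Bcl2l1 and 0.19 for Cd83, with confidence limits between -0.40 and 0.44. NF-kB targets were lower (median -0.06) and MHC class II (0.08), cholesterol synthesis (0.08) and NK cell genes (0.11) higher in camera, and with an estimated correlation had adjusted p = 0.34, 0.26, 0.45 and 0.26. The count was 1 without Ab_60mer replicates 2 or 3 or BRFc_60mer replicate 2, 6 without BRFc_60mer replicate 1 and 0 when only these groups were fitted, where B3gnt7 had adjusted p = 0.154. Spp1 did not pass without Ab_60mer replicates 1 (0.122), 2 (0.0529) or 3 (0.0548) or BRFc_60mer replicates 2 (0.164) or 3 (0.133), nor Pkib without Ab_60mer replicates 2 (0.0529) or 3 (0.0548) or BRFc_60mer replicate 2 (0.0893).

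The interactions test whether mBaffR-mFc changes the response to BAFF. For BAFF 60mer a single gene passed (limma; 640 genes at an unadjusted p under 0.05). This was B3gnt7, whose response was higher under mBaffR-mFc by 0.60 ± 0.089 on the log2 scale (adjusted p = 0.0468; SE). Spp1 (1.09 ± 0.196; adjusted p = 0.234), Casp6 (0.43 ± 0.084) and Pex16 (0.41 ± 0.088) did not pass. The panel lay between -0.20 for Bcl2l1 and 0.29 for Cd83, with confidence limits between -0.42 and 0.68. Cholesterol synthesis genes (median 0.08) were higher and interferon genes (-0.20) lower in camera, with adjusted p = 0.75 and 0.87 with an estimated correlation. The count was 0 without any 1 of the 12 libraries, with an adjusted p for B3gnt7 of 0.0561 to 0.246. For BAFF 3mer no gene passed (limma, 0 also with voom; 560 genes at an unadjusted p under 0.05), with Stambpl1 (0.37 ± 0.073), Apobec2 (-0.71 ± 0.147) and Wdr73 (0.26 ± 0.063) at the smallest p-values. Oxidative phosphorylation (0.93 with an estimated correlation) and ribosomal proteins (0.93) were higher in camera, and the count was 1 without Ab replicate 1 or Ab_3mer replicate 3.

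Across genes, which are not independent replicates, the responses to BAFF 60mer under control antibody and under mBaffR-mFc had a Pearson correlation of 0.58 over 11646 genes. Their libraries are separate, and 0 of 100 simulated sets without change gave as high a value (mean -0.023, SD 0.228), but both responses lie across the split of connective tissue transcripts. The slope of the second on the first was 0.52 among the 1628 called genes, chosen on the first, and 1558 of them had the same sign. Of the genes higher in each, 107 were shared where 8.6 would be by chance, and of those lower 294 where 35.1 would be. Kynu, Nfkbie, Birc3, Cd44, Pim2, Fcer2a, S1pr1, Sdc1 and Klf2 were called the same way in both. The responses to BAFF 3mer and BAFF 60mer under control antibody had a correlation of 0.51. Simulated sets without change that share their control libraries in the same way had a mean of 0.491 and SD of 0.176. Since BAFF 60mer did change genes, these correlations are not directly comparable. The covariance was 0.0131 under control antibody and 0.00709 under mBaffR-mFc, beside a simulated mean of 0.00839. Without a spread for the simulated covariance, these values leave open whether the responses share more than their control libraries. With no library shared, the 563 genes called under mBaffR-mFc were at 0.042 ± 0.029 for BAFF 3mer under control antibody (adjusted p = 0.3, fry of limma). The responses to BAFF 3mer under control antibody and under mBaffR-mFc, from separate libraries, had a correlation of 0.099, and 30 of 100 simulated sets gave as high a value. A shared response was thus not shown.

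The main genes lie, on GRCm38, on chromosome 2 from 43555329 to 43682715 for Kynu, on chromosome 3 from 115710433 to 115715072 for S1pr1, on chromosome 12 from 8771323 to 8793715 for Sdc1 and on chromosome 1 from 86302832 to 86307305 for B3gnt7. In the table they are ENSMUSG00000026866 for Kynu, ENSMUSG00000045092 for S1pr1, ENSMUSG00000020592 for Sdc1 and ENSMUSG00000079445 for B3gnt7, and the annotation gives each as protein coding.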

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

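The tests in this part other than the splits of the samples were chosen after results were seen.

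B3gnt7 stood out because the test of the difference between responses found it: 1 gene passed the interaction of BAFF 60mer with mBaffR-mFc, by 0.596 on the log2 scale. With the library total as a covariate its interaction was 0.595 ± 0.091, against 0.596 ± 0.089 without; the call ended (adjusted p = 0.0791), since it was near the threshold, but the size argues against library size as its source. After removing trends with GC content and length it was 0.536 ± 0.109 and the call ended (adjusted p = 0.325; range over all settings that ended it 0.056 to 0.325), as the spread grew, so part of it could come from there. RNA of connective tissue differs by a log2 ratio of only 0.2 between BRFc_60mer and Ab_60mer, less than 0.59 for B3gnt7 itself, which argues against that source. Chance was not excluded, since 18 of 100 splits of the 12 libraries gave at least 1 gene and the highest other 4, and an effect of mBaffR-mFc on the response of B3gnt7 stays a hypothesis.

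Connective tissue transcripts are a signal outside the groups: their sum had a mean of 10.11 FPKM in the 8 carrying libraries, 0.00156% of all FPKM there, beside 0.04 in the other 10, and fat and mammary gland transcripts followed them, at 3.67 to 6.1 FPKM against 0.05 to 0.24. The split may mark a batch that the labels do not name, and the only group with libraries of both kinds, Ab_3mer with 2 against 1, is too small to settle it. Suppose such a batch were the whole cause of the genes called between BAFF 60mer and no BAFF, which lie across the split. The 563 genes called under mBaffR-mFc would then not differ between Ab_60mer and the carrying Ab_3mer libraries. Yet their mean difference there in the called direction was 0.234 ± 0.031. It was 0.249 ± 0.019 with the position in the order of deposition as a block, since the carrying Ab_3mer libraries lack position 3. Against no BAFF the mean was 0.297 ± 0.029 under control antibody. Under mBaffR-mFc, where the genes were chosen, it was 0.347 ± 0.029. With the library total as a covariate 624 genes passed, 591 of them among the 1628, and after removing trends with GC content and length 1434 passed, 1069 of them among the 1628, which argues against either as the whole cause. A call lost among carrying libraries does not by itself point to a batch, since differences such as that of Bcl2l11 (-0.19) stayed near those against no BAFF, while for Gpr183 (0.006; 0.06 ± 0.059 with the block), Cd83 (-0.04; 0.05 ± 0.056) and Tnfrsf14 (0.003; -0.02 ± 0.111) a batch stays open, because no carrying library lacks BAFF.

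The lower type I interferon genes after BAFF 60mer under mBaffR-mFc, with a mean of -0.408 ± 0.158, could come from such a batch. The list did not pass fry (adjusted p = 0.059) or camera with an estimated correlation. Within BRFc, replicate 3 was highest for Irf7 (30.4 FPKM, beside 17.8 and 22.6) and Mx1 (5.96, beside 4.02 and 4.56), but not for Bst2 or Ifi27l2a. Without BRFc replicate 3, as without each other library of the comparison in turn, the list still passed camera with the preset correlation as lower. Its mean without that library is not given here. Carrying and other Ab_3mer libraries differed by -0.187 ± 0.241, with 2 libraries against 1 that also differ in position, and Ab_60mer differed from the carrying ones by -0.032 ± 0.18, or -0.126 ± 0.126 with the block. A batch and the treatment cannot be told apart for this list, since none of these differences exceeds its standard error.

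Splits of the same libraries into other groups bear on each count. Those of 3 against 3 number 10, too few for a share under 0.05; the number with a count as large as the real one was 1 for BAFF 60mer against no BAFF (1628 genes; highest other 0) and against BAFF 3mer (560; 0) under control antibody. It was 1 under mBaffR-mFc also (563 and 601; 0 in both), and 1 for mBaffR-mFc with BAFF 60mer (3; highest other 1). By construction, as the real count was 0, it was 10 for BAFF 3mer against no BAFF under either pretreatment and for mBaffR-mFc with BAFF 3mer (0; highest other 0), and 10 for mBaffR-mFc without BAFF (0; highest other 1). For the BAFF 3mer interaction, also with a count of 0, it was 100 of 100 by construction (highest other 1), which says nothing about chance. For the F test 1 of 100 gave at least 1040 genes (highest other 67), so a random division of the libraries was excluded there, but not the split by connective tissue transcripts.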

How the results depend on the processing

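Among the alternatives, the library total, first residual component and connective tissue terms, voom, the GC and length correction, the block and the fit without carrying Ab_3mer libraries were added after seeing the data; except where a fit used fewer libraries or terms that follow the groups, the cause of a change was not tested. With quality weights the F test gave 1942 genes, BAFF 60mer against no BAFF and against BAFF 3mer under mBaffR-mFc 1386 and 1318, and mBaffR-mFc with BAFF 60mer 8. With the library total the F test gave 502, BAFF 60mer against no BAFF 624 (control antibody) and 272 (mBaffR-mFc), and against BAFF 3mer 165 under control antibody. With the first residual component these were 2191, 2640, 1187 and 1304, with 1061 against BAFF 3mer under mBaffR-mFc and 10 for mBaffR-mFc with BAFF 60mer. With the connective tissue term, which rests on 2 against 1 libraries, they were 50, 16, 10, 246 and 15; for no BAFF (control antibody, mBaffR-mFc) and BAFF 3mer under mBaffR-mFc the called genes kept medians of 0.223, 0.25 and 0.245 (0.287, 0.318 and 0.295 without it) while the median standard error went from 0.078 to 0.14, so the lost calls by themselves do not point to a batch. In the same order, fitting only the groups compared gave 1053, 139, 252 and 287 for the comparisons of BAFF 60mer, 0 for mBaffR-mFc with BAFF 60mer, 2 for mBaffR-mFc with BAFF 3mer and 2 for BAFF 3mer under mBaffR-mFc. With the position in the order of deposition as a block, the comparisons of BAFF 60mer gave, in that order, 2428, 1105, 1099 and 943. The F test gave 1871 and mBaffR-mFc with BAFF 60mer 4. BAFF 3mer and the other comparisons with a count of 0 stayed at 0, and the BAFF 60mer interaction at 1. All 177 differences of named genes kept their side of the threshold, which is no check of their size. Each group has 1 library at each position, so the block leaves the log2 differences as they were and changes only their standard errors. For BAFF 60mer against no BAFF under control antibody the median standard error went from 0.078 to 0.07. The position in the order of deposition followed 27.4% of the residual variation, against at most 26.9% in 1000 random orders. Of 45 pairs of libraries at the same position 19 had correlated deviations over 0.1 (from -0.07 to 0.39). Of 18 libraries 14 correlated best with their own position, and 952 genes differed between positions (limma, F test, adjusted p under 0.05). The deviations thus followed the position, though the labels state no pairing. The main counts and p-values come from the fit without it. BAFF 3mer under control antibody, its interaction and mBaffR-mFc with BAFF 3mer each gave 1 with no filter, with the connective tissue term and without the carrying Ab_3mer libraries. The BAFF 60mer interaction gave 0 with no filter, median-of-ratios rescaling, the library total, the GC and length correction or only its own groups, and 2 with the connective tissue term. Camera with an estimated correlation called 3 lists for BAFF 60mer against no BAFF under control antibody and 3 under mBaffR-mFc. Leaving out 1 library gave 671 to 1160 genes in the F test. BAFF 60mer against no BAFF gave 756 to 1668 (control antibody) and 242 to 731 (mBaffR-mFc), and against BAFF 3mer 246 to 471 and 233 to 543. mBaffR-mFc with BAFF 60mer gave 1 to 6 and its interaction 0, the other comparisons and interaction 0 to 1, and the lists 4 to 11 and 11 to 14. Signs turned with the connective tissue term for Col3a1 after BAFF 60mer, to -0.34 (control antibody), -0.11 and, against BAFF 3mer, -0.14. Under control antibody, uncalled genes near 0 also turned: Mcl1 to 0.003 (median-of-ratios), 0.049 (library total), 0.044 (GC and length), 0.067 (connective tissue term), and 0.001 and 0.004 without Ab replicate 2 or Ab_60mer replicate 1 (range from -0.048); Relb to -0.004 without Ab replicate 2 (range to 0.045); and Tnfrsf13c to 0.051 (GC and length). The mean of ribosomal proteins after BAFF 60mer under mBaffR-mFc turned to -0.057 without BRFc replicate 3 (range to 0.129). Of 177 differences of named genes, all kept their side of the threshold with pseudocount 0.1 and with the first residual component. That component comes from deviations within groups, so like the block it leaves the log2 differences as they were. With the connective tissue term 116 fell below it, with the library total 19, and with only the groups compared 32. With a minimum of 5 FPKM the correlations across genes were 0.682 for both pretreatments and 0.553 for both forms of BAFF. Depth limits genes near 1 FPKM, and of simulated interactions of 1.5-fold 65.5% were recovered, and of the smallest ones simulated 25.1%.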

Other observations

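The tests on sets of called genes below, and their bounds, were chosen after the results were seen, among 30 tests in the same family. Several lists fixed beforehand did not pass camera after BAFF 60mer under control antibody. Of 28 oxidative phosphorylation genes 0 passed (median 0.01; adjusted p = 0.73 in camera). Of 15 MHC class I genes 2 rose and 1 fell (0.91), of 12 class switching genes 0 passed (0.56), of 13 heat shock genes 2 rose (0.4), of 20 genes of the unfolded protein response 1 rose and 1 fell (0.91) and of 8 immunoglobulin constant genes 0 passed (0.91). Among markers of other cells, 1 of 9 T cell genes (0.4), 1 of 13 macrophage genes (0.4) and 1 of 6 platelet genes (0.33) fell, 0 of 9 neutrophil genes passed (0.91), and Col3a1 was the 1 of 3 stromal genes that rose (0.73). The dendritic cell list had adjusted p = 0.73. Of the RNA quality lists, 1 of 12 mitochondrially encoded genes rose (0.075), 0 of 74 ribosomal protein genes passed (0.38) and 1 of 30 replication histones fell (0.23).

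Genes called after BAFF 60mer under control antibody had a mean of 0.012 ± 0.034 in the called direction for BAFF 3mer under mBaffR-mFc, beside 0.188 ± 0.034 for BAFF 60mer there. A response to BAFF 3mer of 25% of that size could be present or absent, since the bound of 2 standard errors reaches 0.08. Over the 2579 genes called for BAFF 60mer on the mean of both pretreatments, the response was 0.278 ± 0.035 under control antibody and 0.218 ± 0.035 under mBaffR-mFc, a difference of -0.06 ± 0.05 (adjusted p = 0.3, fry of limma). The response under mBaffR-mFc exceeded 50% of the other by 0.079 ± 0.039, at the border of 2 standard errors (adjusted p = 0.091, fry of limma). The genes and their signs were chosen on the mean of these same responses. That choice leans this excess upward, and its standard error and p-value do not allow for it. In this fit, without the position in the order of deposition as a block, a reduction by 50% is neither shown nor excluded. This comparison was not run with that block. Of the other sets, 51 NF-kB genes were at -0.041 ± 0.021 between mBaffR-mFc and control antibody with BAFF 60mer (adjusted p = 0.077, fry of limma), while their interaction, which tests the response itself, was 0.012 ± 0.029 (adjusted p = 0.92). Between BAFF 60mer and BAFF 3mer among carrying libraries they were at 0.132 ± 0.022 (adjusted p = 2.9e-05). The 2579 genes were at 0.074 ± 0.035 for BAFF 3mer under control antibody (adjusted p = 0.091), where the set was chosen with the same Ab libraries, and immediate early genes at -0.28 ± 0.117 among carrying libraries (adjusted p = 0.022). With the position in the order of deposition as a block, a family of 6 tests, the last and the NF-kB genes among carrying libraries were at -0.233 ± 0.076 and 0.143 ± 0.008 (adjusted p = 0.0071 and 3.1e-07, fry of limma). In camera with an estimated correlation, immediate early genes did not pass among carrying libraries without or with the block (adjusted p = 0.38 and 0.4).

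Libraries of the same group had correlations across genes of 0.9918 to 0.9953 over 10447 genes. Their mean squared difference over the variance from counting alone ran from 3.13 to 18.5. It was highest for BRFc replicates 1 and 3 (18.5), BRFc_60mer replicates 1 and 3 (14.9) and BRFc replicates 2 and 3 (13.9).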
